A study of Sus scrofa with 13 samples.

How the data were processed

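Total RNA from myocardial drill biopsies of 13 miniswine was copied into biotin-labelled cRNA and hybridised to Affymetrix porcine arrays, per the labels' protocols. The labels put 6 animals in the saline group and 7 in the stem cell group. Replicate numbers 1 to 6 occur in both groups, are not said to pair animals and are used here only to name them.

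The deposited values are probe set intensities on a linear scale, made by the authors with GCRMA, per the submitters' processing notes. GCRMA corrects the background of Affymetrix arrays, normalizes between arrays and summarises the probes of a set. It gives log2 values, so the deposited intensities had been turned back to a linear scale. Its version and settings, and any further scaling, are not given in the sources used here. Because normalization between arrays makes the distributions alike, a change shared by most genes cannot be seen in these values. Intensities were deposited to about 3 significant digits.

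The table held 24123 probe sets. A set of 124 control probe sets was left out of the tests, and the other 23999 were put on the log2 scale. In the platform annotation 10069 of these had 1 gene symbol, 198 had several and 13732 had none. A probe set with no symbol is unnamed here, not without a gene, and probe sets with several symbols were not named. Symbols were matched by gene ID to a pig gene table of the assembly Sscrofa11.1 for 9961 probe sets, and 0 symbols changed. That assembly was used for names and gene spans, and no coordinates are given since no build is stated for the array. Symbols in the annotation can be old.

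Probe sets were tested where their mean log2 value over all 13 arrays lay above the 40th percentile, a level of 3.36. The highest mean among 17 tag control probe sets, which have no porcine target, was 2.58, and 0 tested probe sets lay at or under it. This left 14399 probe sets, 6884 with 1 symbol, 146 with several and 7369 with none, and 5196 genes.

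The groups were compared in R 4.3.3 with limma 3.58.1, using lmFit and eBayes with a trend of the variance with intensity, and p-values were adjusted by the method of Benjamini and Hochberg with a threshold of 0.05. The median SE of a log2 difference was 0.18, and the median 95% interval reached 0.383 to either side. On simulated data with independent noise, 20 draws of 14399 probe sets with 200 changed in each, the fit recovered 21.7% of changes of 0.5 on the log2 scale, 71% of changes of 1 and 95.8% of changes of 2, and called 0.05% of unchanged probe sets.

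Of 49 gene lists fixed before the data were examined, 44 had at least 5 measured members and were tested with limma's camera at a preset correlation of 0.01 between genes, with 1 probe set per gene, the one with the highest mean. Camera with an estimated correlation, fry and an exact permutation test of the list means over all 1716 splits were run beside it. In simulated data a list shifted by -0.3 was called in 20 of 20 draws, with 5 calls among 43 other lists over those draws. The simulated genes were independent, which real genes of a list are not. Whole-profile separation and the spread between animals were tested by exact permutation over the same splits.

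Named genes followed a rule fixed beforehand: genes past the threshold, filled up to 24 by the smallest p; up to 4 members with the smallest p in each list described; and 18 heart genes whatever their value. A gene with several probe sets was represented by the one with the highest mean, or among the 24 by the probe set with the smallest p.

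Alternatives fixed beforehand were no filter, a filter at the 60th percentile, a second quantile normalization, centring each array on its median, leaving out each animal, a replicate block, a covariate for tissue makeup (the sarcomere mean minus the fibrillar collagen and matrix mean), a variance without trend, a robust variance, array weights, a floor at the 20th percentile, an adjusted p of 0.10, 1 probe set per gene, scaling of each probe set to an SD of 1, and the other list tests. Chosen after seeing the data were leaving out each animal for the members passing over their list alone, camera against all probe sets, the exact permutation of list means, leaving out the 3 arrays at the ends of the first component, and the 3' to 5' control ratio as a covariate. The same groups were also set against 100 splits of the arrays.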

Results

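RNA levels were measured in heart muscle taken by drill biopsy from 13 female Sinclair miniswine, a small breed of pig, after an experimental myocardial infarction. Diagonal branches of the left anterior descending coronary artery had been tied off permanently. Of the animals, 7 had then received 50000000 stem cells in 2 ml saline, spread over 5 sites in the border zone around the infarct, and 6 had received 2 ml saline alone. Biopsies were taken at month 4. Where each biopsy lay relative to the infarct and its border zone is not given per animal. Each animal gave 1 porcine gene expression array, so the animal was the replicate and the number of arrays limits the precision of every value. The median intensity per array lay between 13.5 and 14, and arrays correlated pairwise at 0.936 to 0.986 over the 14399 probe sets tested. No batch or date was given in the labels, and no comparison within batches could be made.

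The design posed a single question: whether gene expression in infarcted hearts at month 4 differed between animals given stem cells and animals given saline. Genes are described first in lists fixed before the data were examined, then one by one. All log2 differences are stem cells minus saline.

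Genes of the mitochondrial respiratory chain were lower on average in hearts that had received stem cells. The oxidative phosphorylation list, which holds subunits of the electron transport complexes and of ATP synthase, averaged a log2 intensity of 12.24 ± 0.21 (SD, n = 7) after stem cells and 12.48 ± 0.11 (SD, n = 6) after saline. Of its 49 measured members, 42 had a negative log2 difference, and 6 of 7 stem cell animals lay below the saline mean. The median log2 difference was -0.226, and -0.147 without stem cells replicate 4. A count of 10 members fell when adjusted over the list alone, and 0 passed when adjusted over all probe sets tested. The complex I subunits NDUFB11, NDUFA2 and NDUFB8 fell by 0.79 ± 0.21, 0.72 ± 0.21 and 0.32 ± 0.098 (log2, SE), and the complex III subunit UQCR10 fell by 0.55 ± 0.16, each with an adjusted p of 0.0382 over the list alone and 0.393 over all probe sets (limma). With 1 animal left out, a check added after these values were seen, the count was 0 without saline replicates 1, 3, 4 or 6 and without stem cells replicates 2, 3, 4 or 6. It was 8 without saline replicate 5, 13 without saline replicate 2 or stem cells replicate 5, 15 without stem cells replicate 1 and 20 without stem cells replicate 7. The members were grouped by complex after the list's values were seen. Negative differences were found in 23 of 24 measured subunits of complex I, 3 of 4 of complex II and 2 of 2 of complex III. They were found in 5 of 5 of complex IV, 9 of 13 of complex V and 0 of 1 gene of cytochrome c.

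Genes of the mitochondrial ribosome, which translates the proteins encoded in mitochondrial DNA, and of mitochondrial biogenesis were lower as well. The list averaged 8.42 ± 0.24 (SD, n = 7) after stem cells and 8.69 ± 0.24 (SD, n = 6) after saline, with 45 of 49 members negative and a median log2 difference of -0.33. At an unadjusted p under 0.05, 17 members were lower and 1 was higher, and 0 passed when adjusted over the list alone or over all probe sets. Over the list alone, 8 members passed without stem cells replicate 7, and 1 without stem cells replicate 1 or 6. The smallest p in this list belonged to TIMM8B, part of a chaperone complex of the space between the mitochondrial membranes, at -0.56 ± 0.15 (SE). The ribosomal proteins MRPS12, MRPS21 and MRPS11 followed at -0.67 ± 0.19, -0.76 ± 0.25 and -0.67 ± 0.23.

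Proteasome subunits, parts of the main protease complex of the cell, averaged 10.03 ± 0.12 (SD, n = 7) after stem cells and 10.19 ± 0.14 (SD, n = 6) after saline. Of 31 members 26 were negative, 9 of them at an unadjusted p under 0.05, and 0 passed when adjusted over the list alone (5 without saline replicate 5) or over all probe sets. The core subunits PSMB2, PSMB5, PSMB3 and PSMA7 had log2 differences of -0.40 ± 0.12, -0.42 ± 0.15, -0.43 ± 0.16 and -0.28 ± 0.11 (SE). Proteins of the cytosolic ribosome averaged 13.45 ± 0.23 (SD, n = 7) and 13.59 ± 0.093 (SD, n = 6). Of these 55 genes 47 were negative, with a median of -0.11 (-0.0651 without stem cells replicate 3). RPLP2, RPS15, RPL38 and RPS29 had values of -0.54 ± 0.22, -0.31 ± 0.14, -0.50 ± 0.23 and -0.50 ± 0.23 (SE), and 0 passed when adjusted over the list alone or over all probe sets.

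These 4 lists were the ones past the threshold among 44 tested, all lower after stem cells, by limma's camera test with a preset correlation between genes. The adjusted p was 6.33e-06 for oxidative phosphorylation, 2.25e-05 for the mitochondrial ribosome and biogenesis, 0.0182 for the proteasome and 0.0312 for cytosolic ribosomal proteins. Each call was lost with an adjusted p = 0.995 with an estimated correlation. An exact permutation test of the list means gave two-sided p of 0.0315, 0.0589, 0.0332 and 0.191 in the same order, with adjusted p of 0.365, 0.432, 0.365 and 0.699, and fry called 0 lists. Camera did not call creatine kinase and phosphate transfer or glycolysis and glucose uptake. Their exact permutation p were smaller than those of the 4 lists, at 0.00408 and 0.0233 (adjusted 0.179 and 0.365). With the preset correlation, 84 of 100 splits of the 13 arrays into groups of 6 and 7, the real split included, called 4 lists or more. The other splits called a median of 8 lists.

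The proteasome call ended without saline replicate 3 (camera adjusted p of 0.11, median of -0.12) and without stem cells replicate 4 (0.0996, median of -0.101). With all animals its median was -0.132. The call of cytosolic ribosomal proteins ended without saline replicates 2 (0.144), 3 (0.11) or 4 (0.0812) and without stem cells replicates 3 (0.633) or 6 (0.154). The medians in those fits were -0.079, -0.115, -0.126, -0.0651 and -0.0744. This call also ended with no filter (0.0721), with the tissue makeup covariate (0.124) and with a variance without trend (0.0936). The median, -0.111 before, stayed at -0.102, -0.0965 and -0.111. Without saline replicate 3 the count of lists was 2. Normalizing the arrays again by quantiles left 2 lists, oxidative phosphorylation and the mitochondrial ribosome. The log2 ratio of the 3' to the 5' control probe set, a measure of RNA integrity, rises as RNA degrades. For actin it was 2.89 after stem cells and 3.13 after saline (exact permutation p of 0.664). For GAPDH it was 1.51 and 1.61 (exact permutation p of 0.24). For EF1A it was 0.815 ± 0.11 (SD, n = 7) after stem cells and 0.947 ± 0.098 (SD, n = 6) after saline. The EF1A ratio had an exact permutation p of 0.046, adjusted to 0.207 over 9 array measures. The hybridisation controls bioD and cre, with log2 means of 14.2 ± 0.13 after stem cells and 14.1 ± 0.099 after saline, had a smaller p (exact permutation p of 0.0396, adjusted 0.207). Genes with a short genomic span were also lower as a class: with genes ranked by span into 3 equal bins, the median log2 difference was -0.17 in the shortest bin and 0.024 in the longest.

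**Figure D1:**
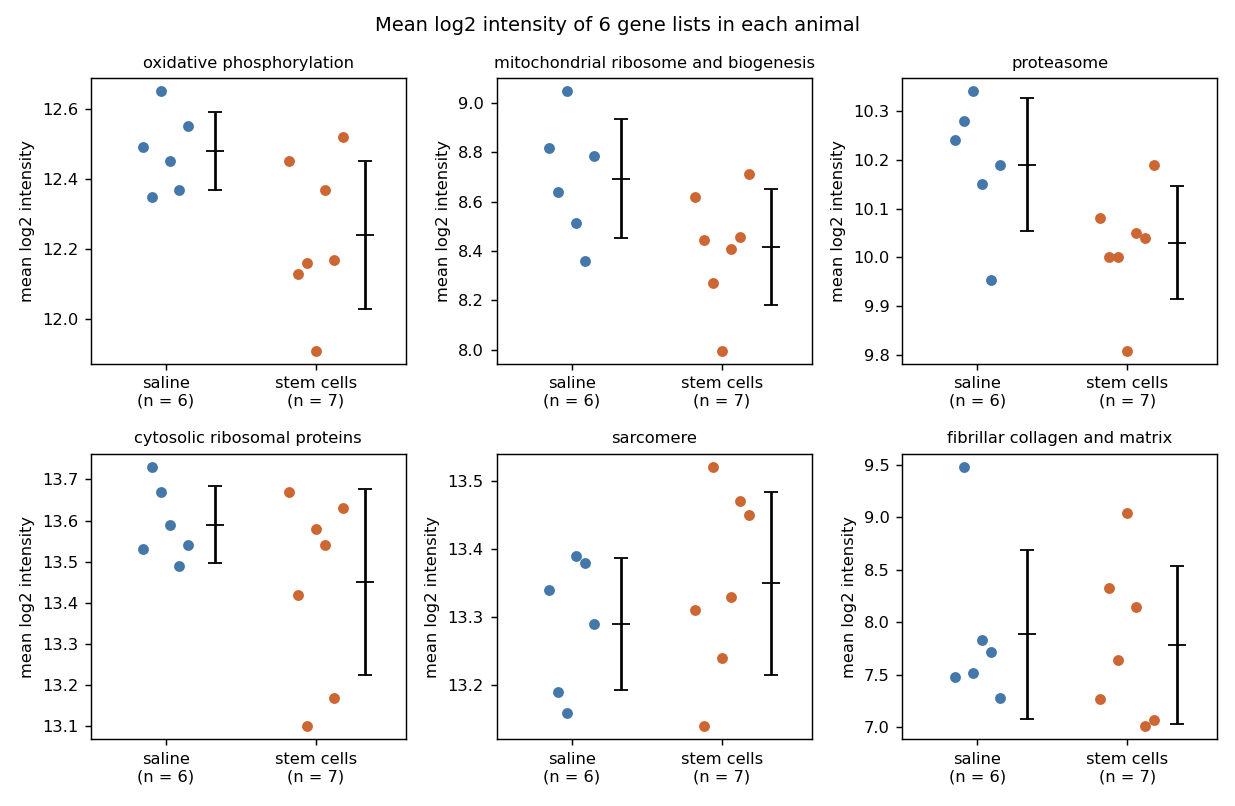
Mean log2 intensity of the members of 6 gene lists (vertical axes) in each of 6 saline and 7 stem cell animals (points), with the group mean and SD (black bars). In the oxidative phosphorylation panel the stem cell animals average 12.24 and the saline animals 12.48, while the groups overlap in every panel.

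Genes of the contractile apparatus were slightly higher on average. The sarcomere list averaged 13.35 ± 0.13 (SD, n = 7) after stem cells and 13.29 ± 0.096 (SD, n = 6) after saline, and 5 of its 17 members were negative (camera adjusted p of 0.0678, 0.995 with an estimated correlation). Camera called it higher without saline replicates 1 (adjusted p of 0.0376) or 5 (0.0103), without stem cells replicates 2 (0.0072) or 4 (0.0253) and with array weights (0.00576). MYOM1, which links myosin filaments in the M-band, had the smallest p in this list at 0.30 ± 0.12 (SE). PDLIM5, cardiac actin ACTC1 and MYOM2 had values of 0.16 ± 0.085, 0.12 ± 0.070 and 0.24 ± 0.16. Of the 13 measured fetal and stress genes of cardiomyocytes, which rise in overloaded hearts, 10 were negative. NPPA and NPPB, encoding the natriuretic peptides, had log2 differences of -0.77 ± 0.39 and -1.50 ± 0.76 (SE), and RCAN1, a target of calcineurin signalling, -0.78 ± 0.40. Without stem cells replicate 6 NPPB was at -0.899 and RCAN1 at -0.477, and without saline replicate 6 NPPA was at -0.449. In this list 0 members passed when adjusted over the list alone or over all probe sets.

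The calcium handling list held the named gene with the smallest p. HRC, a calcium-binding protein of the sarcoplasmic reticulum, had a log2 intensity of 6.43 ± 0.50 (SD, n = 7) after stem cells and 7.67 ± 0.23 (SD, n = 6) after saline. It fell by 1.23 ± 0.22 (log2, SE) adjusted over the list alone (0.000597) and did not pass over all probe sets (0.393, limma). All 7 stem cell animals lay below all 6 saline animals. The kinase subunit CAMK2D was at 0.36 ± 0.13, while FKBP1B, which binds the ryanodine receptor, was at -0.59 ± 0.23 and S100A1 at -0.68 ± 0.30 (-0.44 without stem cells replicate 6). The 12 members went both ways, 6 of them negative. Camera gave an adjusted p of 0.987, whereas fry's test for change in either direction gave 0.00919, the only list of 44 past the threshold in it. Among 8 cardiac transcription factors, MEF2A and GATA6 rose when adjusted over the list alone, by 0.77 ± 0.17 and 0.45 ± 0.14 (adjusted p of 0.00321 and 0.0252, and 0.393 and 0.404 over all probe sets). GATA6 no longer passed over its list without saline replicates 2 or 5 or without stem cells replicates 3, 5, 6 or 7 (adjusted p of 0.0695 at most). GATA4 and HAND1 had values of -0.29 ± 0.16 and -0.15 ± 0.15, HAND1 at -0.0725 without saline replicate 1 and -0.246 without saline replicate 2.

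Among genes of energy transfer and fuel use, CKB, the brain-type creatine kinase, fell by 0.94 ± 0.28 (log2, SE) when adjusted over the creatine kinase and phosphate transfer list alone (0.0487, and 0.393 over all probe sets). It passed in 3 of 13 fits with 1 animal left out, those without saline replicates 1 or 3 or stem cells replicate 1, and its adjusted p reached 0.143 in the others. SLC6A8, GAMT and SLC25A5 of the same list were at -0.47 ± 0.24, -0.21 ± 0.15 and -0.26 ± 0.20, with SLC6A8 at -0.309 without saline replicate 5 and SLC25A5 at -0.159 without stem cells replicate 5. The mean of that list, 10.90 ± 0.087 (SD, n = 7) after stem cells and 11.05 ± 0.056 (SD, n = 6) after saline, had an exact permutation p of 0.00408, which became 0.179 when adjusted over 44 lists, and camera gave an adjusted p of 0.838. Of 18 genes of glycolysis and glucose uptake 16 were negative, among them glycogen synthase GYS1 at -0.81 ± 0.23, PFKP at -0.53 ± 0.24, ALDOC at -0.43 ± 0.20 and PDK4 at -0.39 ± 0.26 (camera adjusted p of 0.214, 0.0289 without stem cells replicate 3, and 0.0371 with the 3' to 5' ratio as a covariate). Of 26 genes of fatty acid uptake and oxidation 18 were negative, with CPT1A at -0.38 ± 0.20, ACADVL at -0.36 ± 0.19, UCP2 at -0.30 ± 0.17 and ETFB at -0.37 ± 0.22 (camera adjusted p of 0.623). Without stem cells replicate 6 PDK4 and UCP2 were at -0.182 and -0.178, and without stem cells replicate 2 ETFB was at -0.239. The 22 genes of the tricarboxylic acid cycle had a median of -0.024 (camera adjusted p of 0.852). In these last 3 lists 0 members passed when adjusted over the list alone (1 of glycolysis without saline replicate 4 or stem cells replicate 7) or over all probe sets.

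Antioxidant genes were mostly lower, 20 of 27 (camera adjusted p of 0.21). GPX1, a glutathione peroxidase, fell by 0.91 ± 0.23 (log2, SE) when adjusted over the list alone (0.032, and 0.393 over all probe sets). It passed in 4 of 13 fits with 1 animal left out, those without saline replicates 1, 4 or 5 or stem cells replicate 7, with an adjusted p of up to 0.102 in the others. PRDX2, SOD1 and PRDX4 were at -0.35 ± 0.11, -0.32 ± 0.13 and -0.30 ± 0.12. Of 32 heat shock and protein folding genes 23 were negative, with the small heat shock proteins HSPB6 and HSPB1 at -0.83 ± 0.26 and -0.54 ± 0.19, HSPE1 at -0.35 ± 0.16 and HSP90AB1 at 0.20 ± 0.099 (camera adjusted p of 0.798). The 22 immediate early genes, which respond within minutes to stress, varied widely between animals. NR4A3, NR4A2, FOSL2 and IER3 had log2 differences of -2.20 ± 0.72, -1.66 ± 0.64, -1.42 ± 0.56 and -1.32 ± 0.80 (SE), and the list's camera adjusted p was 0.798. The list rested largely on stem cells replicate 6: without that animal its mean log2 difference went from -0.444 to -0.057 and its median turned from -0.246 to 0.113, while the 4 genes were at -1.90 ± 0.71, -1.27 ± 0.55, -1.18 ± 0.55 and -0.62 ± 0.51 (SE). In the last 2 lists 0 members passed when adjusted over the list alone (1 heat shock gene without saline replicate 3, 2 immediate early genes without saline replicate 1) or over all probe sets.

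For scar matrix, fibroblasts, macrophages and the interferon response, no list passed with all 13 animals against the other named genes. Fibrillar collagen and matrix genes averaged 7.78 ± 0.75 (SD, n = 7) after stem cells and 7.88 ± 0.80 (SD, n = 6) after saline (camera adjusted p of 0.799). In this list COL3A1 and COL1A2 were at 0.35 ± 0.12 and 0.31 ± 0.20, SERPINH1, a collagen chaperone, at -0.61 ± 0.30 and COL6A2 at -0.39 ± 0.25 (SE). COL1A2 was at 0.158 without stem cells replicate 5, and COL6A2 at -0.222 without saline replicate 2. The probe sets of COL3A1 and COL1A2 had mean log2 intensities under 4, not far above the level of 3.36 that the filter required. Fibroblast and myofibroblast markers averaged 10.02 ± 0.60 and 10.09 ± 0.60 (camera adjusted p of 0.987). Of 17 macrophage and monocyte markers 14 were negative, with TYROBP, AIF1, FCER1G and LAPTM5 at -0.77 ± 0.30, -0.65 ± 0.29, -0.70 ± 0.36 and -0.35 ± 0.29 (camera adjusted p of 0.52). Camera called these markers lower without stem cells replicate 4 (0.0248), and LAPTM5 was at -0.208 without saline replicate 5 and -0.228 without stem cells replicate 2. Of 22 interferon response genes 8 were negative, with MX2 at 0.81 ± 0.27, IFI44L at 0.91 ± 0.43, GBP1 at -0.50 ± 0.31 and GBP2 at -0.66 ± 0.44 (camera adjusted p of 0.214). The interferon list was called higher without saline replicate 4 (0.0264) and without stem cells replicates 4 (0.0221) or 6 (0.00799). With an estimated correlation and all animals, the adjusted p was 0.995 for both lists. Without saline replicate 4 GBP1 and GBP2 were at -0.326 and -0.382, and without saline replicate 6 IFI44L was at 0.592.

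Endothelial markers were negative in 12 of 16 (camera adjusted p of 0.799), with the receptor TEK at 0.38 ± 0.17, ENG at -0.65 ± 0.29, ECSCR at -0.73 ± 0.36 and MCAM at -0.78 ± 0.42 (SE). In the notch signalling list, NOTCH4, a receptor of vascular endothelium, fell by 0.57 ± 0.15 when adjusted over the list alone (0.0201, and 0.393 over all probe sets), while DLL4, JAG1 and RBPJ were at -0.29 ± 0.10, 0.32 ± 0.15 and 0.25 ± 0.17, RBPJ at 0.155 without saline replicate 6. The 14 angiogenic and paracrine factors, 12 smooth muscle and pericyte markers and 10 stem and progenitor cell markers had medians of -0.15, -0.10 and -0.056, with camera adjusted p of 0.947 for each. In the collagen, macrophage, interferon and endothelial lists 0 members passed when adjusted over the list alone (1 interferon gene without saline replicate 4 or stem cells replicate 4) or over all probe sets.

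Over all 44 lists, 16 members passed when adjusted over their list alone, 2 higher and 14 lower, against 0 over all probe sets. HRC, MEF2A and NOTCH4 passed over their lists in 13 of 13 fits with 1 animal left out. The total of 16 became 10 without saline replicate 1, 8 without saline replicate 4, 6 without saline replicates 3 or 6 or stem cells replicate 4, 5 without stem cells replicate 2, 4 without stem cells replicates 3 or 6, and 34 without stem cells replicate 7. The 40 lists not past the camera threshold had adjusted p from 0.0678 to 0.987, and of 0.995 each with an estimated correlation. Against all probe sets as the background, a choice made after seeing the data, 6 more were called lower: glycolysis (0.00889), antioxidant defence (0.00379), macrophage markers (0.0453), fatty acid oxidation (0.0453), heat shock and the cell cycle (0.0473 each). That background includes probe sets with no symbol, whose median was 0.061 against -0.054 for genes with a symbol. It therefore moves any list of named genes toward lower. NF-kB signalling was called higher with array weights (0.022). In 14 lists, calcium handling, the cardiac transcription factors, fibrillar collagen, fibroblast markers, angiogenic factors and the tricarboxylic acid cycle among them, the median or the mean was negative where camera gave higher. Camera compares the moderated t statistics of a list with those of the other genes, whose median log2 difference was -0.054. That median does not account for all of these signs. Calcium handling, with a median of -0.079 and a mean of -0.152, lay below it on both and was still given as higher. A further 5 lists, of lymphocyte, neutrophil and mast cell, erythroid and platelet, mesothelial and epicardial, and cartilage and bone markers, had fewer than 5 measured members and were not tested.

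By single genes, 0 of 14399 probe sets passed an adjusted p of 0.05 in limma, and the smallest adjusted p was 0.393. At an unadjusted p under 0.05 there were 1519 probe sets, 777 higher and 742 lower after stem cells, where chance alone would give 720. Among genes with a symbol, 151 were higher and 465 lower at that level. The 24 genes with the smallest p, all with a symbol, held 5 higher and 19 lower. Besides MEF2A the higher ones were SENP6, a SUMO protease, at 0.68 ± 0.15 (SE), GTDC1 at 0.42 ± 0.095, SNRNP48, a protein of the minor spliceosome, at 0.66 ± 0.16, and KIAA1429 at 0.87 ± 0.22. After HRC, the smallest p among the lower ones belonged to PPP1R14A, an inhibitor of myosin phosphatase in smooth muscle, at -0.66 ± 0.13, RNASEK at -0.85 ± 0.17, ELOF1 at -0.64 ± 0.13, INHA at -0.58 ± 0.13 and VPS28 at -0.64 ± 0.14. FSTL3, which binds activin, was at -1.06 ± 0.27, SLC25A33, a mitochondrial nucleotide carrier, at -1.04 ± 0.25, MYL9, a myosin light chain of smooth muscle, at -0.88 ± 0.22, and BMP1, which trims procollagen, at -0.40 ± 0.097. PPP1R14A (3.84 after saline and 3.18 after stem cells), INHA (3.98 and 3.4), GTDC1 (3.53 and 3.95) and BMP1 (4.14 and 3.75) had mean log2 intensities near the filter level of 3.36. The others, MSMB, CYP19A3, SWI5, HDGF, ERGIC1, ATP6V1F, CDK16, AVPI1 and GPX1, lay between -0.96 and -0.66. Other probe sets of these genes had differences of the same sign, larger for BMP1 (-0.48) and smaller for the rest: 0.44 and 0.24 for SENP6, 0.29 for MEF2A, 0.17 for GTDC1, 0.092 for KIAA1429, -0.54 for AVPI1, -0.10 for CYP19A3, and -0.078 and -0.13 for CDK16.

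Without saline replicate 5 a single probe set passed, that of HIGD1B, named after its values were seen, with a log2 difference of -0.72 ± 0.092 (SE) and an adjusted p of 0.0222, against -0.49 and 0.423 with all animals.

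For the heart genes named in advance, the intervals gave the sizes that the probe set used for each could still hold. For the contractile and calcium cycling genes MYH7, TNNI3, ATP2A2 and PLN the log2 differences were 0.072 (95% interval -0.073 to 0.22), 0.038 (-0.11 to 0.18), 0.14 (-0.077 to 0.35) and 0.21 (-0.033 to 0.46). The muscle and mitochondrial creatine kinases CKM and CKMT2 were at 0.073 (-0.069 to 0.21) and -0.13 (-0.36 to 0.10). PPARGC1A, a coactivator of mitochondrial gene expression, was at -0.037 (-0.53 to 0.46), VEGFA at 0.21 (-0.068 to 0.50), PECAM1 at 0.070 (-0.33 to 0.47) and ACTA2 at 0.077 (-0.56 to 0.71). The signs of PPARGC1A, PECAM1 and ACTA2 turned when some animals were left out. The matrix genes POSTN and SPP1 had the widest intervals but for NPPB, at 0.50 (-0.98 to 1.98) and -0.65 (-2.25 to 0.95), and the second probe set of POSTN was at -0.12. With 1 animal left out, POSTN ranged from 0.126 (without saline replicate 6) to 0.902 (without saline replicate 2), and SPP1 from -1.09 (without stem cells replicate 4) to -0.136 (without saline replicate 2). Other moves by over 1.5 times were MYH7 to 0.0436 without saline replicate 6 and 0.0449 without stem cells replicate 3, ATP2A2 to 0.0857 and 0.079 without stem cells replicates 3 and 6, PLN to 0.133 without saline replicate 2, CKM to 0.0477 without saline replicate 3, CKMT2 to -0.2 and -0.084 without saline or stem cells replicate 4, and VEGFA to 0.139 without stem cells replicate 6. TNNI3 lay between 0.018 (without stem cells replicate 7) and 0.0596 (without stem cells replicates 2 or 5). Other probe sets of VEGFA were at 0.098 and -0.11, those of ATP2A2 at 0.337 and 0.34, that of PLN at 0.078 and that of PECAM1 at 0.000496. None of these heart genes passed over all probe sets. KDR had 2 probe sets, both under the filter, and MYH6 and COL1A1 had no probe set with that name.

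**Figure D2:**
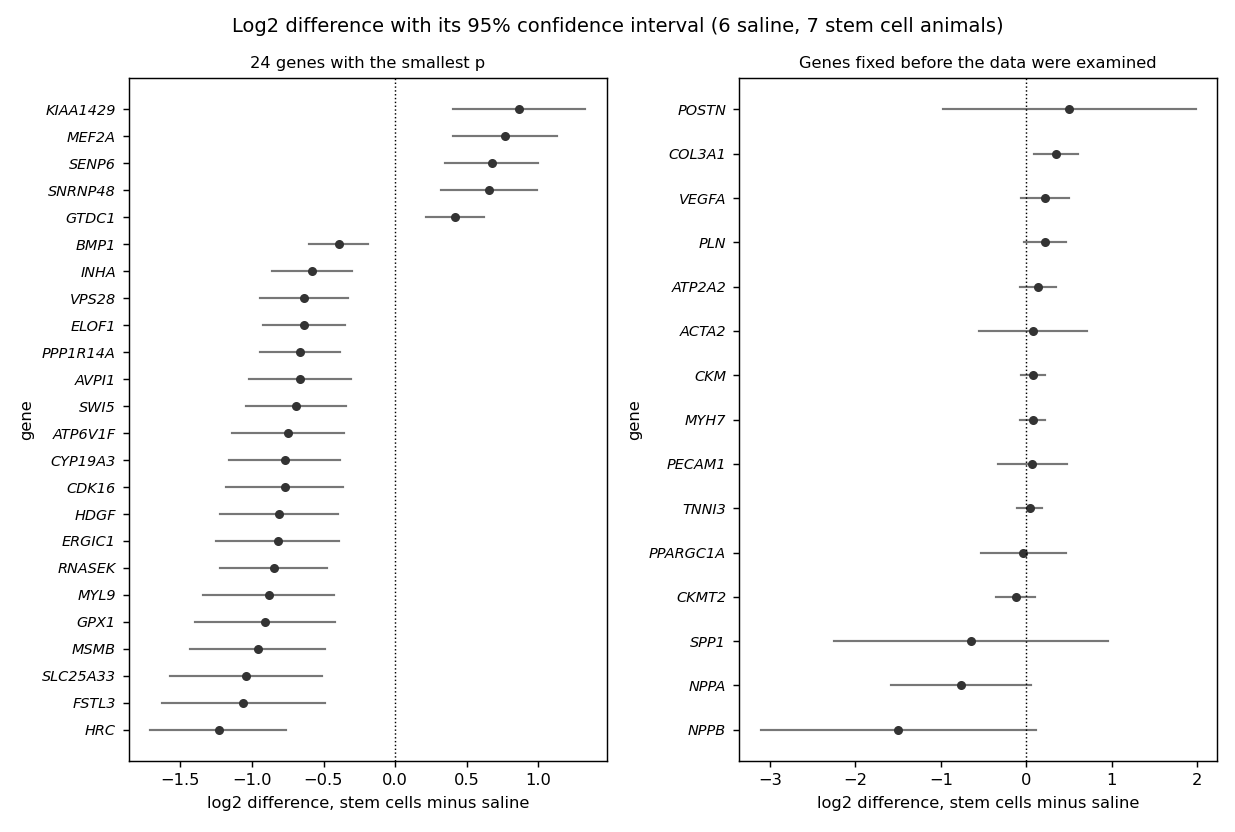
Log2 difference in intensity, stem cells minus saline (horizontal axes), with the 95% confidence interval of limma's fit (lines), for the 24 genes with the smallest p (left) and for 15 heart genes fixed in advance (right), from 6 saline and 7 stem cell animals. On the left 5 genes lie above 0 and 19 below it, and the smallest adjusted p is 0.393. Of all genes with a symbol, 151 were higher and 465 lower at an unadjusted p under 0.05 (limma).

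Separation of the groups in the profile as a whole did not pass its test. The share of the total sum of squares that lay between them was 10.9%, against a median of 7.94% over the 1716 possible splits (exact permutation p of 0.161). The same held for the spread between animals, where the median log2 ratio of variances, stem cells over saline, was 0.105 (two-sided exact permutation p of 0.79), with a median SD per probe set of 0.313 after stem cells and 0.294 after saline. The first principal component held 24.7% of the variance. Saline replicates 5 and 6 lay at one end of it, with scores of 40.2 and 44.4, and stem cells replicate 6 at the other with -62.4. Group means on it were -10.9 ± 26.3 (SD, n = 7) and 12.8 ± 23 (SD, n = 6), an exact permutation p of 0.119. Without those 3 arrays, a choice made after seeing the data, 0 probe sets passed and 9 lists did by camera. The 4 named above were again lower, and 5 were higher relative to the other genes: sarcomere (adjusted p of 0.0183), NF-kB signalling (0.00203), angiogenic and paracrine factors (0.00203), cytokines and chemokines (0.0223, with a negative median of -0.122) and immediate early genes (0.000206).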

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

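Of the tests in this part, those of RNA degradation, of the number of cardiomyocytes, of the per-animal difference from genes matched on span, and of the number of splits with probe sets past the threshold were chosen only after the result was seen. For the RNA degradation test, the limit for the upper end of the interval of oxidative phosphorylation was moved from -0.117 to 0 after that end had been seen, and under the first limit degradation stays open there.

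In 63 measures, each looked at in both groups, 6 times an animal lay far from the others of its group, where chance gives about 6.3. MEF2A stood at 8.63 in saline replicate 6, with the nearest saline animal at 9.1. PLN stood at 13.5 in saline replicate 2, with the nearest at 13.9. The mean of the fibrillar collagen and matrix list was 9.48 in saline replicate 2, with the nearest at 7.83, and the second principal component had a score of 43.5 in the same animal, with the nearest at 4.51. The mean of the macrophage and monocyte markers was 7.93 in stem cells replicate 4, with the nearest at 7.06. The mean of the immediate early genes was 7.05 in stem cells replicate 6, with the nearest at 9.55.

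The 4 lists called by camera were lower after stem cells, but 84 of 100 splits of the arrays, the real one included, called as many lists. The other splits called a median of 8 lists and at most 23. The real grouping thus called fewer than usual, and chance is not excluded. Whether the biopsies held fewer cardiomyocytes cannot be settled for oxidative phosphorylation. The sarcomere score minus that of oxidative phosphorylation was higher after stem cells by 0.295 (exact permutation p of 0.0233, not adjusted). A loss shared equally by both lists would not give this. Of the 44 lists, however, sarcomere had the smallest camera p among those higher and oxidative phosphorylation among those lower. A gap between them was therefore partly built in by the choice. For oxidative phosphorylation, RNA degradation as the whole cause is argued against only as the mean of the actin, GAPDH and EF1A ratios measures it. With that mean 3' to 5' control ratio as a covariate, the list's mean difference was -0.258. Its 95% interval lay under 0 (upper end -0.0399). Actin varied most in that mean, with an SD of 1.11 after stem cells and 0.744 after saline. The SDs of EF1A were 0.107 and 0.0984. EF1A was not tried as a covariate by itself, so degradation as EF1A shows it stays open. For the other lists degradation cannot be told apart. With the covariate the mitochondrial ribosome was at -0.273 (-0.279 without it) and the proteasome at -0.165 (-0.167 without it). Cytosolic ribosomal proteins were at -0.131 (-0.147 without it). The covariate moved the first of these little, but the intervals reached 0.045, 0.00255 and 0.102 in that order. Camera with the covariate called oxidative phosphorylation, the mitochondrial ribosome and the proteasome (adjusted p of 2.91e-06, 0.000268 and 0.0404) and not cytosolic ribosomal proteins (0.48). The mean 3' to 5' log2 ratio, which rises as RNA degrades, was 1.74 after stem cells and 1.9 after saline (exact permutation p of 0.481). Lower values of short genes may account for the proteasome and cytosolic ribosomal lists. A share of 0.211 and 0.51 of 10000 random lists matched on gene span and intensity had a median as low. For oxidative phosphorylation and the mitochondrial ribosome it was 0.0001 for each, the smallest that many lists can give. That was under the limit of 0.05 set beforehand, which goes against gene span. Random lists, however, lack the variation between animals that genes of a list share. Per animal, the gap between each of the latter 2 lists and its matched genes differed between the groups by -0.137 and -0.136 (exact permutation p of 0.128 and 0.27), so gene span stays open for them too, as does an effect of the cells themselves.

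Genes with a symbol were lower and probe sets with no symbol higher after stem cells, with medians of -0.054 and 0.061 and a difference of 0.115. At an unadjusted p under 0.05, 465 genes with a symbol were lower and 151 higher, against 222 and 538 of the probe sets with no symbol. A difference in intensity level is argued against, since the gap averaged 0.136 within 10 bins of intensity and had the same sign in 10 of them. A trend with gene span may contribute: among genes with a symbol the longest bin lay above the shortest by 0.193, though the spans of unnamed probe sets are not known here. Chance is not excluded, since 5 of 100 splits gave a gap as large (0.13 at most among the others), and 6 of 100 a span trend as large, the real split included in both; no biological explanation was tested.

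The 1519 probe sets at an unadjusted p under 0.05 exceeded the 720 that independent probe sets would give. Of 100 splits, the real one included, 12 gave as many, and the highest of the others gave 2739, so that chance is not excluded. For the 0 probe sets past the adjusted threshold the splits say nothing about chance, since any split gives at least as many (100 of 100, with 1 at most among the others).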

How the results depend on the processing

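The leave-out of animals for list members, camera against all probe sets, the exact permutation of list means, the fit without 3 arrays and the 3' to 5' ratio covariate were chosen after seeing the data. The count of probe sets past the threshold was 0 under every alternative except leaving out 1 animal, where it ranged from 0 to 1 (1 without saline replicate 5). At an unadjusted p under 0.05 the count ranged from 1026 to 1788 with 1 animal left out, and was 622 with 1 probe set per gene, where fewer were tested. The 4 lists became 2 after a second quantile normalization, 3 with no filter, with the makeup covariate and with a variance without trend, 6 with array weights, 0 with an estimated correlation, 0 by fry, 0 by exact permutation, 10 with all probe sets as the background and 9 without the 3 arrays at the ends of the first component; with 1 animal left out they ranged from 2 to 6. Oxidative phosphorylation and the mitochondrial ribosome passed in 13 of 13 such fits, the proteasome in 11 and cytosolic ribosomal proteins in 8; the median of each list stayed negative throughout. With the replicate block, which left out stem cells replicate 7, 0 probe sets and 4 lists passed. The labels do not say that the numbers pair animals. Same-numbered animals deviated together at r over 0.1 in 1 of 6 pairs (mean r of -0.0929), and 0 correlated best with their own number. These values gave no sign of pairing but cannot exclude it. The 16 list members past the threshold over their list alone ranged from 4 to 34 with 1 animal left out. Whole-profile separation stayed between 9.53% and 13.1%, with exact permutation p from 0.0676 to 0.368. The spread ratio, 0.105, was -0.0551 with no filter and from -0.0939 to 0.355 with 1 animal left out, all with permutation p of 0.295 or more. Among 2689 values of 108 named genes, 0 passed and 13 changed sign, in 3 genes. PPARGC1A was at 0.00225 with the replicate block and at the same value without stem cells replicate 7 alone. Its sign with the block thus came with leaving out that animal. With 1 animal left out PPARGC1A ranged from -0.182 to 0.0727. PECAM1 was at -0.0792 and ACTA2 at -0.0317 without the 3 arrays. They ranged from -0.0159 to 0.196 and from -0.0967 to 0.321 with 1 animal left out. By over 1.5 times, 30 of 108 named genes moved with some animal left out, 12 of them without stem cells replicate 6, and 0 of the 24 with the smallest p. The cause was not tested for these changes. The median log2 difference of all probe sets lay between -0.021 and 0.031 over the alternatives. Signal over background limits probe sets near the filter level of 3.36, and the collagens COL3A1 and COL1A2, PPP1R14A, INHA, GTDC1 and BMP1 are among them.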

Other observations

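Matrix and macrophage genes differed more between animals than between the group means. The fibrillar collagen and matrix mean reached 9.48 in saline replicate 2 and 9.04 in stem cells replicate 4, while the lowest, in stem cells replicate 6, was 7.01. Macrophage and monocyte markers were highest in the same animals, at 7.96 in saline replicate 2 and 7.93 in stem cells replicate 4.

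Across the 13 animals, 4 relations between list means were computed, all chosen after seeing the data. Where no adjusted p is given below it was 0.0913 for r and 0.0825 for rho. Matrix and macrophage means gave Pearson's r of 0.822 (permutation p of 0.00135, adjusted 0.0054) and Spearman's rho of 0.648 (permutation p of 0.0197, adjusted 0.0788). Without saline replicate 2 and stem cells replicate 4, the animals farthest from the matrix median, r was 0.41, so the relation rests on those animals. SPP1 was a member of both the matrix and the macrophage list, so part of their relation was built in. Matrix and sarcomere means gave r of -0.553 (permutation p of 0.0503, adjusted 0.0913) and rho of -0.505 (permutation p of 0.0825), with r of -0.432 without the same animals. Matrix and oxidative phosphorylation means gave r of -0.486 (permutation p of 0.0913) and rho of -0.516 (permutation p of 0.0749), with r of -0.333 without them. Interferon response and MHC class II means gave r of 0.511 (permutation p of 0.0749) and rho of 0.571 (permutation p of 0.0449, adjusted 0.0825), with r of 0.424 without saline replicate 6 and stem cells replicate 4. The interferon response and MHC class II lists as fixed share PSMB9 and TAP1, so part of that relation may be built in as well.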
